A study of Mus musculus with 12 samples.

How the data were processed

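Gene expression was measured by RNA sequencing in lower motor neurons cut by laser from the lumbar spinal cord of C57BL/6 mice aged 5 months. The mice were wild type, heterozygous or homozygous for a knock-in of Q331K, an amino acid change in TDP-43 found in people with amyotrophic lateral sclerosis (ALS). TDP-43 is an RNA-binding protein encoded by Tardbp. Each genotype had 4 libraries, 12 in all. The labels do not say whether each library came from its own animal, so the p-values measure the spread between libraries. Per the labels, RNA was extracted with a kit for laser-captured cells, copied by a template-switching kit for very low input and made into libraries with a transposase kit. These kits add no molecular identifiers, so reads were not independent molecules, and the count floors used here cover counting error only. The kits also keep no strand information, and genes that overlap on opposite strands can share reads.

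The deposited values are raw counts per gene, which the authors made from reads trimmed with Trim Galore 0.4.3 and aligned with HISAT2 2.0.5 to mouse genome build GRCm38. The counting program, its annotation release and its strand setting were not given in the sources used here. The table held 25965 entries, and 66 of them repeated a gene symbol used by another and were kept as separate entries. At least 1 count was found for 20011 entries, and each entry is counted here as a gene. Entries with the same start and end as a gene in GENCODE release M21 numbered 14867 of 25965 (57.3%), and identifiers are given only for those. Total counts per library ran from 60886825 to 83504446. The smallest chi-square per degree of freedom between libraries of the same genotype was 62 over 18 pairs. Libraries of the same genotype therefore differed by far more than counting error, and none was a repeat run of another of its genotype. Pairs of different genotypes were not tested in this way.

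Genes were kept by the filterByExpr function of edgeR 4.0.16 in R 4.3.3, which left 16338. Counts were scaled by the TMM method, with factors from 0.94 to 1.03, and are given as CPM, the usual share of a gene in the scaled library total. Log2 CPM values used a prior count of 2. A quasi-likelihood model over all 12 libraries with the 3 genotypes as groups gave the comparisons between each pair of genotypes and a test of any genotype difference. A further model took the number of mutant alleles (0, 1 or 2) as a slope. All tests were two-sided, and the Benjamini-Hochberg adjusted p had to be below 0.05. The biological coefficient of variation was 0.57. Intervals are 95% confidence intervals from the same model. Where all libraries of a genotype had 0 counts, the fold is a lower bound against a floor of 3 counts over the group.

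Before the data were examined, 46 gene lists were written down: 12 of cell type markers, 32 of pathways or functions and 2 linked to sex. The 45 lists with 3 or more tested members were compared with all other genes by camera in limma 3.58.1, with a preset correlation between genes of 0.01, and adjusted together within each comparison. Each was tested again with an estimated correlation and with fry, which asks whether a list's genes move on balance in a single direction. Cell type content was the mean log2 CPM of each marker list per library. Library quality was taken from total counts, genes detected, the share of the 10 most abundant genes and the share of mitochondrially encoded genes. Both were compared between genotypes by exact two-sided permutation tests of 4 against 4 libraries, where the smallest possible p is 0.0286.

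The rule for naming genes was also fixed before the data were examined. Tardbp was always named. Where fewer than 5 genes passed in a comparison of a pair of genotypes, all that passed and the 10 smallest p-values were named. The 5 smallest p-values in each direction were named for the allele slope and for any genotype difference. Up to 4 members with the smallest p were named for a gene list, as were the most abundant markers of a cell type. Genes named outside the rule are said to be so.

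The fitting steps were tested on simulated counts for all 12 libraries, of which 15851 genes passed the filter. Changed genes had the full change in homozygotes and a smaller change in heterozygotes. Between homozygotes and wild type, the edgeR model recovered 9.68% of genes changed 1.5-fold, 27.9% of those changed 2-fold and 66.2% of those changed 4-fold. At 32 CPM or more these shares were 19.4%, 63.2% and 100%. False calls numbered 4 with edgeR, 36 with DESeq2 1.42.0 and 1 with limma-voom. The alternatives tried were DESeq2 and limma-voom with quality weights, the size factors of DESeq2, no filter and a stricter filter, the replicate number as a block, the number of genes detected as a covariate, only the 8 libraries compared, and leaving out each library in turn. Leaving out heterozygote replicate 1 and homozygote replicate 1 together, a covariate for interneuron content, and the mitochondrial list without its 6 most variable genes were added after the data were seen. No library was left out otherwise. The counts carry no information on splicing or on the mutated base, so neither was analysed here.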

Results

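Lower motor neurons were profiled in 12 libraries, 4 from wild type mice, 4 from mice heterozygous for Q331K and 4 from homozygotes. Total counts of wild type replicates 1 to 4 were 76501269, 62908120, 66398171 and 83504446. The heterozygote libraries held 75409460, 78842784, 65322527 and 72700747 counts, and the homozygote libraries 73369776, 67751858, 60886825 and 74788288. The comparisons asked which transcripts differ in motor neurons that carry 1 or 2 mutant copies of Tardbp.

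The motor neuron transcripts Nefh and Chat were found in all 12 libraries. Nefh, the heavy neurofilament chain, averaged 4440 ± 897 CPM (SD, n = 4) in wild type, 4900 ± 1380 CPM in heterozygotes and 4980 ± 1310 CPM in homozygotes (n = 4 each). Chat, the enzyme that makes acetylcholine, averaged 130 ± 78.4, 177 ± 120 and 201 ± 86.4 CPM (SD, n = 4 each) in the same order. The captured material also held RNA of other cells. In wild type, the myelin gene Mbp averaged 762 ± 463 CPM, the astrocyte enzyme Aldoc 1080 ± 171 CPM, the glutamate transporter of excitatory neurons Slc17a6 269 ± 42.0 CPM and the glycine transporter of inhibitory neurons Slc6a5 203 ± 89.3 CPM (SD, n = 4 each).

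Heterozygote replicate 1 and homozygote replicate 1 stood apart from the other 10 libraries in interneuron and motor neuron markers. Slc17a6 was at 0.563 CPM in the first and 4.52 CPM in the second, against 160 to 323 CPM in the others. Slc6a5 was at 1.35 and 0 CPM against 123 to 293 CPM, and Slc32a1, the vesicular transporter of GABA and glycine, at 0.845 and 0.638 CPM against 34.2 to 100 CPM. Of 19 motor neuron markers, 13 lay above the range of the other 10 libraries in both. Chodl, a marker of fast motor neurons, was at 1490 and 1460 CPM against 191 to 574 CPM, and Chat at 353 and 329 CPM against 63.5 to 241 CPM. Esrrg went the other way, at 41 and 43.8 CPM against 44.7 to 81.4 CPM. Esrrb was low in homozygote replicate 1 alone (1.2 CPM against 5.26 to 8.11 CPM). Gfra1, Isl1 and Ret lay within the range, and Ache lay above it in heterozygote replicate 1 alone. These genes were chosen from the marker lists after the values were seen. The oligodendrocyte scores of both libraries (5.18 and 5.32) lay within those of the others (4.43 to 5.8). Their astrocyte scores (3.83 and 3.93) did too (3.55 to 5.23), although Aldoc was lower, at 467 and 511 CPM against 791 to 1280 CPM. The first principal component, with 23.5% of the variance, set these libraries apart from the others. The root mean square difference was 0.33 log2 CPM between them, 0.51 to 0.68 between either and another library, and at most 0.45 among the other 10.

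**Figure D1:**
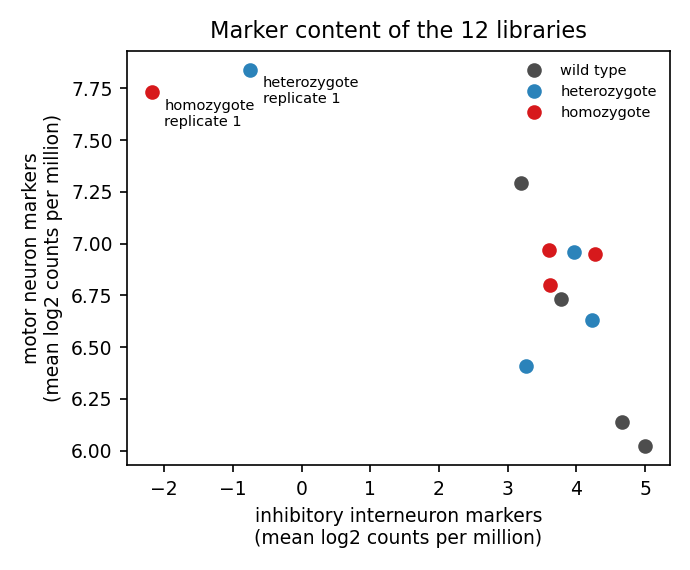
Mean log2 CPM of 10 inhibitory interneuron markers (horizontal axis) against that of 19 motor neuron markers (vertical axis), with a point for each of the 12 libraries coloured by genotype. Heterozygote replicate 1 (-0.75) and homozygote replicate 1 (-2.18) lie far to the left of the others, which start at 3.20.

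The cell type scores were compared between genotypes, but with 4 against 4 libraries a single list at the smallest possible exact p of 0.0286 has an adjusted p of 0.343 over 12 lists, so no list could pass alone. The inhibitory interneuron score was 4.16 ± 0.82 in wild type, 2.67 ± 2.32 in heterozygotes and 2.33 ± 3.02 in homozygotes (mean log2 CPM, SD, n = 4 each), and the exact permutation p was 0.286 for either mutant against wild type. The endothelial markers had a log2 difference of -0.75 between heterozygotes and wild type (exact permutation p = 0.0286), but 0.08 when their CPM were summed first (exact permutation p = 0.229). That sum was mostly Bsg (863 ± 34.9 CPM in wild type) and Itm2a (141 ± 74.6 CPM), so it says little of the other endothelial markers. The oligodendrocyte markers differed by 0.42 between the mutants (exact permutation p = 0.0857), and by 0.43 when their CPM were summed first (exact permutation p = 0.0286). Genes detected averaged 16790 ± 187 in wild type, 16610 ± 198 in heterozygotes and 16590 ± 245 in homozygotes (SD, n = 4 each), with an exact permutation p of 0.286 for either mutant against wild type.

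Tardbp RNA was at the same level in the 3 genotypes within the spread between libraries. It averaged 73.7 ± 7.7 CPM in wild type, 73.0 ± 5.5 CPM in heterozygotes and 75.6 ± 2.2 CPM in homozygotes (SD, n = 4 each). Tardbp (ENSMUSG00000041459) lies on the minus strand of chromosome 4, from 148612382 to 148627019 in GRCm38, and had 4685 to 6544 counts per library. The edgeR log2 difference between homozygotes and wild type was 0.04 (SE 0.09, 95% interval -0.17 to 0.24, adjusted p = 1), which as a fold spans 0.89 to 1.18. Heterozygotes differed from wild type by -0.01 (interval -0.22 to 0.19), and homozygotes from heterozygotes by 0.05 (interval -0.15 to 0.25). The exact permutation p was 0.914 for homozygotes and 0.886 for heterozygotes against wild type, and 0.486 between the mutants. Tardbp overlaps Masp2 on the other strand, whose counts came to 7.5% of those of Tardbp. The difference of -0.03 without wild type replicate 1 had the opposite sign, and that of heterozygotes against wild type also turned without wild type replicates 2, 3 or 4 (0.03, 0.01 and 0.02) or heterozygote replicate 4 (0.04), all far inside the intervals.

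Homozygotes were compared with wild type to ask what 2 mutant copies change. Spop, which carries substrates to the cullin 3 ubiquitin ligase, fell 1.52-fold, from 164 ± 6.2 CPM in wild type to 108 ± 6.4 CPM in homozygotes (SD, n = 4 each). The homozygote libraries lay between 100 and 115 CPM and the wild type libraries between 157 and 172 CPM. Spop (ENSMUSG00000057522) lies on the plus strand of chromosome 11, from 95414080 to 95493406, overlaps no other gene in the table and had 6282 to 13220 counts per library. Its log2 difference was -0.61 (SE 0.07, 95% interval -0.76 to -0.45, adjusted p = 0.0192 in edgeR).

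**Figure D2:**
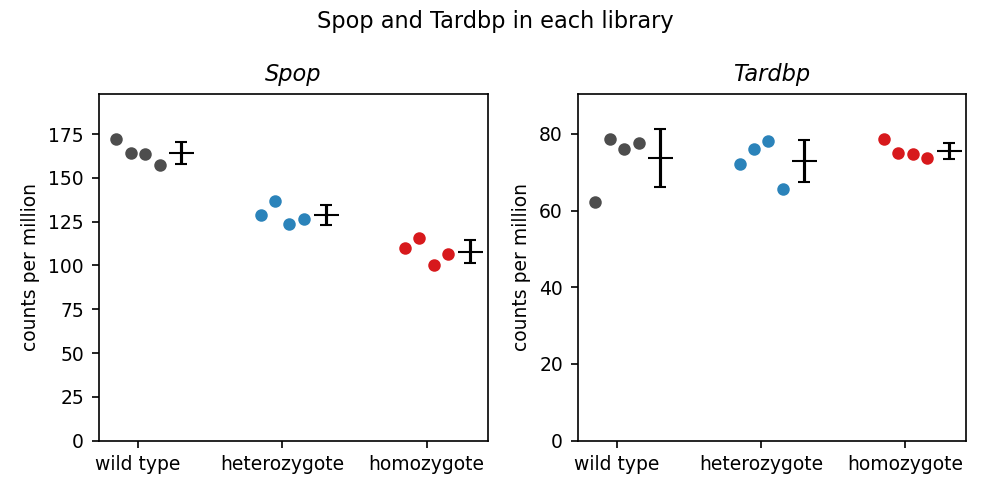
CPM of Spop and Tardbp in each library by genotype, with 4 points per genotype, the mean as a horizontal line and the SD as a bar. Spop was lower in every mutant library (100 to 137 CPM) than in every wild type library (157 to 172 CPM), while the genotypes overlapped for Tardbp.

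Of 16338 genes tested in homozygotes against wild type, Spop alone passed, with 0 higher and 1 lower. At an unadjusted p below 0.05 there were 804 genes, against 817 expected by chance. DESeq2 called 13 genes and limma-voom 1. The edgeR call ended in 12 of 22 alternative settings, although the difference stayed between -0.57 and -0.64, and the adjusted p ran from 9.81e-12 to 0.263. It ended on leaving out any wild type library, heterozygote replicates 3 or 4, or homozygote replicates 1, 3 or 4, and then 0 genes were called.

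The next smallest p-values in homozygotes against wild type belonged to genes that did not pass in edgeR. Magee1, a member of the melanoma antigen family, averaged 258 ± 10.0 CPM in wild type and 203 ± 13.7 CPM in homozygotes, and Spock2, an extracellular proteoglycan, 272 ± 6.98 and 223 ± 5.31 CPM (SD, n = 4 each). Aox1, an aldehyde oxidase, averaged 6.07 ± 0.642 and 19.7 ± 7.05 CPM, and 2900097C17Rik 3.13 ± 1.45 and 9.25 ± 1.64 CPM. Wwp2, a ubiquitin ligase overlapped by a pseudogene with few counts, was at a log2 difference of -0.62 (SE 0.14), and Pnmal1 at -1.21 (SE 0.25). Scn2a1, the alpha subunit of a neuronal sodium channel, averaged 15.9 ± 3.26 and 29.5 ± 4.23 CPM. It was the 1 gene in any list that passed when adjusted over the list alone (adjusted p = 0.00661 in edgeR, among sodium and calcium channel genes, against 0.9 over all genes). Lrrc9 had 16 to 116 counts in each wild type library and 0 in all homozygote libraries, at least 80.7-fold lower. Rps4y2, at 63.2 ± 10.5 and 36.1 ± 7.06 CPM, is uncertain because its position is that of a processed pseudogene inside Tmtc1.

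Synaptic vesicle and release genes fell as a list in homozygotes. Of 38 members, 31 were lower than in wild type, with a mean log2 difference of -0.30 (camera adjusted p = 0.00119, adjusted p = 0.881 with an estimated correlation). Nsf, the ATPase that recycles fusion complexes, averaged 1340 ± 28.0 CPM in wild type and 1120 ± 99.8 CPM in homozygotes (SD, n = 4 each). Glycolysis genes fell, with 13 of 17 lower and a mean of -0.13 (adjusted p = 0.0377, adjusted p = 0.881 with an estimated correlation), among them Pkm at -0.19 (SE 0.06) and Eno2 at -0.15 (SE 0.06). All 10 inhibitory interneuron markers were lower, with a mean of -1.83 (adjusted p = 0.0377, adjusted p = 0.881 with an estimated correlation), and Gad1, which makes GABA, averaged 17.4 ± 7.84 and 2.99 ± 2.61 CPM (SD, n = 4 each). Motor neuron markers passed as a higher list, with 16 of 19 higher and a mean of 0.57 (adjusted p = 0.00603, adjusted p = 0.881 with an estimated correlation). Between libraries, the exact permutation p of the motor neuron score was 0.2. No member passed singly, and fry called 0 lists.

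Without homozygote replicate 1, the library almost free of interneuron RNA, none of the 4 lists passed. The means were then -0.12 for synaptic vesicle genes, -0.33 for inhibitory interneurons and 0.37 for motor neurons, while that for glycolysis moved less, to -0.10. The last pair also missed the threshold without wild type replicate 3 (-1.55 and 0.40) or 4 (-1.66 and 0.44). Glycolysis missed it too without wild type replicates 1 (-0.08), 3 (-0.12) or 4 (-0.14), heterozygote replicates 2 or 3 (-0.13 each) or homozygote replicate 3 (-0.09). Without heterozygote replicate 1 and homozygote replicate 1 together, 0 genes and 2 lists passed, the synaptic vesicle (-0.12, adjusted p = 0.00874) and glycolysis genes (-0.10, adjusted p = 0.0291).

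Other lists passed in homozygotes when single libraries were left out. Without wild type replicate 1 these were the mitochondrially encoded (-1.57), oxidative phosphorylation (-0.09), nerve injury (0.26) and cholesterol synthesis genes (0.19), and without wild type replicate 2 the astrocyte markers (-0.44). Without wild type replicate 3 they were the oligodendrocyte (0.28), oligodendrocyte precursor (1.64) and ribosomal lists (0.07), and without homozygote replicate 2 the microglia (0.82) and ribosomal lists (0.09). Red blood cell markers passed as higher without heterozygote replicate 4 (0.98) or homozygote replicate 3 (1.33).

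Heterozygotes were compared with wild type to ask what a single mutant copy changes. In edgeR no single gene passed, while DESeq2 called 9, among them Spop, Tshz2, Btaf1, Lpar1, Samd4, Gfpt2 and 2900097C17Rik. Spop averaged 129 ± 5.8 CPM in heterozygotes against 164 ± 6.2 CPM in wild type (SD, n = 4 each), a log2 difference of -0.35 (SE 0.07, adjusted p = 0.999 in edgeR). Tshz2, a zinc finger transcription factor, averaged 29.2 ± 2.63 CPM in wild type and 16.7 ± 2.72 CPM in heterozygotes, and Btaf1, which removes the TATA-binding protein from DNA, 24.6 ± 2.72 and 12.3 ± 4.31 CPM. Lpar1, a receptor for lysophosphatidic acid, averaged 7.81 ± 3.52 and 2.43 ± 0.492 CPM, and Samd4, a translational repressor, 17.4 ± 1.55 and 10.5 ± 1.81 CPM. Gfpt2, an enzyme of the hexosamine pathway, had 56 to 138 counts in each wild type library, 1 count in heterozygote replicate 1 and 0 in the other heterozygote libraries. The zinc finger gene Zfp182 averaged 1.86 ± 0.679 and 5.32 ± 1.98 CPM, and 2900097C17Rik 3.13 ± 1.45 and 9.37 ± 1.97 CPM. Bcas1 (53.8 ± 20.8 and 28.9 ± 1.59 CPM) and 8430419L09Rik (223 ± 20.6 and 176 ± 8.29 CPM) overlap other genes and are uncertain.

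In heterozygotes against wild type edgeR called 0 of 16338 genes, with 673 at an unadjusted p below 0.05, and limma-voom also called 0. Cd14, a receptor for bacterial lipopolysaccharide, was the 1 list member that passed when adjusted over the list alone (adjusted p = 0.0386 in edgeR, among reactive glia and complement genes). It had 25 to 77 counts in each wild type library and 0 in all heterozygote libraries, at least 56.9-fold lower.

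Astrocyte and oligodendrocyte markers passed as lower lists in heterozygotes, while 13 of 18 microglia markers were higher (mean log2 difference 0.44, camera adjusted p = 0.128). Compared between libraries, the scores did not separate the genotypes. The exact permutation p was 0.257 for astrocyte and 0.4 for oligodendrocyte markers. Of 16 astrocyte markers, 15 were lower, with a mean log2 difference of -0.53 (camera adjusted p = 0.00104, adjusted p = 0.944 with an estimated correlation). Agt, angiotensinogen, averaged 15.3 ± 8.33 CPM in wild type and 7.36 ± 2.96 CPM in heterozygotes (SD, n = 4 each). Of 19 oligodendrocyte markers, 17 were lower, with a mean of -0.32 (adjusted p = 0.0204, adjusted p = 0.959 with an estimated correlation), and the myelin genes Mbp and Mobp were at -0.79 (SE 0.30) and -0.89 (SE 0.36). Wild type replicate 3 held these 2 genes at 1440 and 465 CPM. The other wild type libraries (455 to 649 and 102 to 199 CPM) overlapped the heterozygotes (412 to 502 and 107 to 141 CPM). Synaptic vesicle genes fell as well, with 31 of 38 lower and a mean of -0.26 (adjusted p = 0.0139, adjusted p = 0.944 with an estimated correlation). Cytosolic ribosomal protein genes rose by a mean of 0.07, with 68 of 78 higher (adjusted p = 0.00104, adjusted p = 0.959 with an estimated correlation), among them Rpl12 at 0.29 (SE 0.14). Motor neuron markers passed as a higher list, with 16 of 19 higher and a mean of 0.42 (adjusted p = 0.0269, adjusted p = 0.959 with an estimated correlation), and fry called 0 lists. Between libraries, the exact permutation p of the motor neuron score was 0.4. All 10 inhibitory interneuron markers were lower (mean -1.49, adjusted p = 0.0668), as were 14 of 17 glycolysis genes (-0.12, adjusted p = 0.0515) and 12 of 14 endothelial markers (-0.75, adjusted p = 0.134), and 18 of 22 cholesterol synthesis genes were higher (0.13, adjusted p = 0.0802). None of these lists passed, and the inhibitory interneuron mean was -0.34 without heterozygote replicate 1 and homozygote replicate 1.

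The heterozygote list calls also rested on single libraries. The motor neuron (0.12) and synaptic vesicle lists (-0.04) no longer passed without heterozygote replicate 1. The motor neuron call ended without wild type replicate 3 (0.25) or 4 (0.29), the synaptic vesicle call without wild type replicate 4 (-0.25), the astrocyte call without wild type replicate 3 (-0.21) and the ribosomal call without wild type replicate 1 (0.02). The oligodendrocyte call ended without wild type replicates 3 (-0.14) or 4 (-0.18) and without heterozygote replicates 2 (-0.19) or 3 (-0.28). Without heterozygote replicate 1 and homozygote replicate 1 together, 4 lists and 0 genes passed: the astrocyte (-0.56), oligodendrocyte (-0.39), ribosomal (0.09) and nuclear-encoded oxidative phosphorylation genes (0.07, adjusted p = 0.0133).

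Other lists passed in heterozygotes when single libraries were left out or the replicate number was a block. Inhibitory interneuron markers passed as lower without wild type replicate 1 (-1.80), heterozygote replicates 2 (adjusted p = 0.0363) or 3 (-1.91) or homozygote replicate 1 (-1.49), and with the block (-1.49, adjusted p = 0.00429). Without heterozygote replicate 1 and homozygote replicate 1 together their mean was -0.34, with 2 of 10 higher (camera adjusted p = 0.518). Glycolysis genes passed as lower without wild type replicate 2 (-0.15) and with the block (-0.12). Microglia markers passed as higher without wild type replicate 1 (0.78, adjusted p = 0.0246) or 3 (0.74, adjusted p = 0.0268). Cholesterol synthesis genes passed as higher without wild type replicate 1 (0.24) or heterozygote replicates 3 (0.17) or 4 (0.22), and with the block (0.13). Mitochondrially encoded genes passed as higher without wild type replicate 2 (1.02) or heterozygote replicate 4 (1.21), nerve injury genes without wild type replicate 1 (0.24) and oxidative phosphorylation genes without heterozygote replicate 1 (0.07).

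The mutant genotypes were compared directly to ask whether a further mutant copy makes a difference. In edgeR no single gene passed, while DESeq2 called Fut4, Gfpt2 and Lrrc9. Zfp592, a zinc finger gene, averaged 12.9 ± 4.17 CPM in heterozygotes and 5.87 ± 1.17 CPM in homozygotes, and Cpne9, a copine, 16.0 ± 8.16 and 5.41 ± 1.60 CPM (SD, n = 4 each). Cnpy4 averaged 12.8 ± 1.64 and 20.5 ± 2.34 CPM, and the fucosyltransferase gene Fut4 0.108 ± 0.127 and 2.21 ± 1.67 CPM. Snapc4, of the complex that drives small nuclear RNA genes, averaged 18.5 ± 5.46 and 9.28 ± 2.82 CPM and is uncertain because another gene overlaps it. Fasl and Cd14 had 0 counts in all heterozygote libraries and were at least 36.3-fold and 34.5-fold higher over the homozygotes, although Fasl had 1 count in homozygote replicate 4 and Cd14 had 0 in homozygote replicate 1. Lrrc9 and Ptger3, a prostaglandin receptor, had 0 counts in all homozygote libraries and were at least 42.3-fold and 35.7-fold lower there. Gfpt2 had 9 to 57 counts in each homozygote library. In edgeR 0 of 16338 genes passed, with 489 at an unadjusted p below 0.05, while DESeq2 called 3 and limma-voom 0.

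Oligodendrocyte and red blood cell markers rose in homozygotes relative to heterozygotes. Of 19 oligodendrocyte markers, 18 were higher, with a mean log2 difference of 0.42 (camera adjusted p = 2.99e-05, adjusted p = 0.975 with an estimated correlation), and Trf, transferrin, averaged 151 ± 30.4 CPM in heterozygotes and 244 ± 57.4 CPM in homozygotes (SD, n = 4 each). All 4 red blood cell markers were higher, with a mean of 1.61 (adjusted p = 0.001, adjusted p = 0.975 with an estimated correlation), among them the heme synthesis gene Alas2 at 0.271 ± 0.255 and 2.28 ± 2.09 CPM. Their score was 3.42 and 4.34 in homozygote replicates 1 and 2, but 2.05 and 2.56 in replicates 3 and 4, against 0.55 to 2.45 in heterozygotes. The exact permutation p was 0.0571 for this score and 0.229 for the summed CPM. The globin genes Hba-a1 and Hba-a2 are near-identical paralogs and are uncertain singly. Mitochondrially encoded genes fell, with 11 of 13 lower, a mean of -1.48 and a median of -0.32 (adjusted p = 0.00215, adjusted p = 0.975 with an estimated correlation). The fry test called 0 lists, and no list member passed when adjusted over the list alone.

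Other cell type markers were also higher in homozygotes than in heterozygotes without passing: astrocyte (14 of 16, mean 0.33, adjusted p = 0.0524), endothelial (10 of 14, 0.57, adjusted p = 0.238) and pericyte and smooth muscle markers (5 of 8, 1.03, adjusted p = 0.238). Astrocyte markers passed without wild type replicates 2 or 3 (0.33 each), heterozygote replicates 3 (0.29) or 4 (0.37) or homozygote replicate 4 (0.47). The motor neuron (0.44), oligodendrocyte precursor (1.39) and oxidative phosphorylation lists (-0.10) passed without heterozygote replicate 1, and without homozygote replicate 1 the cholesterol synthesis (-0.18), axonal transport (-0.07) and ribosomal lists (-0.07). Axonal transport genes also passed without heterozygote replicates 3 or 4 (-0.08 each), and ribosomal genes without heterozygote replicate 3 (-0.05).

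The mitochondrial difference came from 6 neighbouring genes, mt-Co2, mt-Atp8, mt-Atp6, mt-Co3, mt-Nd3 and mt-Nd4l, from position 7013 to 10173 of the mitochondrial chromosome. Across the 12 libraries their highest CPM was 122 to 521 times their lowest. For mt-Co3, a subunit of cytochrome oxidase, the range was 5.28 to 2580 CPM. The other 7 genes summed to between 6600 and 8630 CPM. Without the 6 genes the list did not pass, at a mean of -0.10 (adjusted p = 0.374), and the number of lists past the threshold was 2. Nor did the list pass without heterozygote replicate 1 (-1.18) or homozygote replicate 4 (-1.10). Without heterozygote replicate 1 and homozygote replicate 1 together, 4 lists and 0 genes passed between the mutants. These were the oligodendrocyte (0.51) and red blood cell markers (1.83), the nuclear-encoded oxidative phosphorylation genes (-0.10, 8 of 78 higher, adjusted p = 0.000196) and the cytosolic ribosomal protein genes (-0.09, adjusted p = 0.000304), while the mitochondrially encoded list was at -0.82 (adjusted p = 0.0915).

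**Figure D3:**
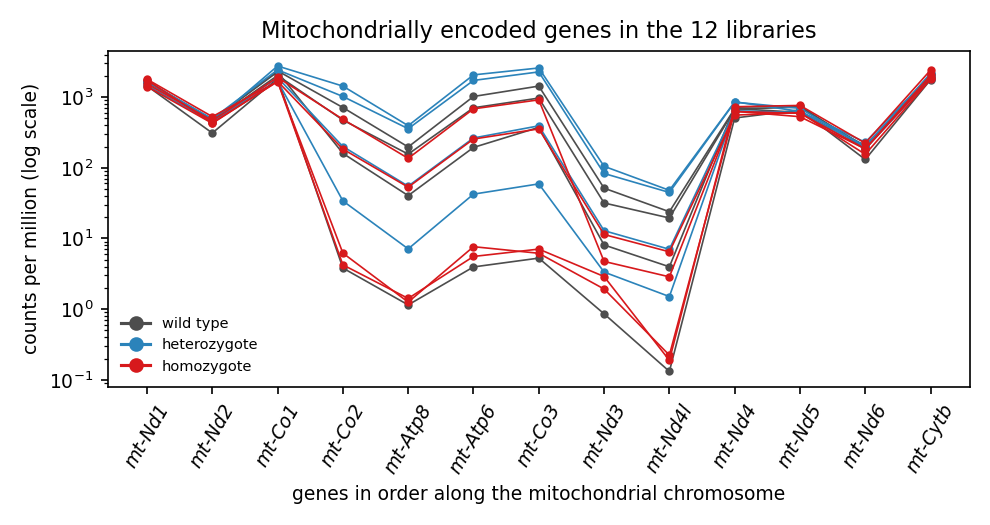
CPM on a log scale of the 13 mitochondrially encoded genes in their order along the chromosome, with a line for each of the 12 libraries coloured by genotype. From mt-Co2 to mt-Nd4l the libraries spread over more than 100-fold, while the other 7 genes lie close together.

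A slope over 0, 1 and 2 mutant alleles was fitted to ask which transcripts follow the number of mutant copies. Spop fell by 0.30 on the log2 scale per allele, a slope of -0.30 (SE 0.03, adjusted p = 0.00762 in edgeR), from 164 ± 6.2 through 129 ± 5.8 to 108 ± 6.4 CPM (SD, n = 4 each). Scn2a1 averaged 15.9 ± 3.26, 22.5 ± 2.86 and 29.5 ± 4.23 CPM in wild type, heterozygotes and homozygotes, and the splicing factor Cwc25 13.7 ± 3.67, 20.1 ± 0.712 and 24.3 ± 2.49 CPM. Saal1 averaged 6.16 ± 0.475, 9.84 ± 3.14 and 12.2 ± 2.28 CPM. Ggt1, which cleaves glutathione, had 55 to 107 counts in each wild type library and 0 in all homozygote libraries, at least 99.5-fold lower. Magee1, Pnmal1, Aox1 and Rps4y2 were again among the smallest p-values, as was Pcdhb20 (6.11 ± 2.05, 7.45 ± 2.16 and 13.9 ± 4.14 CPM), which is uncertain within its cluster of paralogs.

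For the slope edgeR called 0 genes higher and 1 lower, with 777 at an unadjusted p below 0.05, while DESeq2 called 12 and limma-voom 1. The Spop slope stayed between -0.29 and -0.32 in 21 alternative settings and passed in 17, with an adjusted p from 1.63e-12 to 0.0651. It missed the threshold without wild type replicate 2 (-0.30) or 3 (-0.30) or homozygote replicate 3 (-0.29) or 4 (-0.30), where 0 genes were called, and without wild type replicate 1 there were 2 calls. Without heterozygote replicate 1 and homozygote replicate 1 together the slope was -0.31 (adjusted p = 0.0295).

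The test of any genotype difference called 0 of 16338 genes in edgeR. Spop had the smallest p (adjusted p = 0.072), and 583 genes had an unadjusted p below 0.05. DESeq2 called 5 genes and limma-voom 0. Ptpn6, a phosphatase of blood cells that overlaps a gene with few counts, averaged 0.0496 ± 0.0992 CPM in wild type, 0.00352 ± 0.00704 CPM in heterozygotes and 0.947 ± 0.413 CPM in homozygotes (SD, n = 4 each).

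Genes tied to ALS and frontotemporal dementia (FTD) did not pass as a list in any comparison. Of 38 members, 22 were higher in homozygotes than in wild type, with a mean log2 difference of 0.05 (camera adjusted p = 0.715). The mean was 0.03 for heterozygotes against wild type (adjusted p = 0.81) and 0.01 between the mutants (adjusted p = 0.977), where the median was -0.01. None of the 38 passed when adjusted over the list alone. Unc13a, a release factor at synapses, averaged 50.6 ± 8.10 CPM in wild type and 40.9 ± 4.51 CPM in homozygotes, and the actin-binding gene Pfn1 203 ± 11.4 and 254 ± 60.1 CPM (SD, n = 4 each). The 30 genes reported to depend on TDP-43 in mouse brain had means of -0.09 in homozygotes (adjusted p = 0.715) and -0.03 in heterozygotes (adjusted p = 0.996, with the test leaning upward) against wild type, and of -0.06 between the mutants (adjusted p = 0.753).

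Other groups that could mark a stressed motor neuron also missed the threshold in homozygotes against wild type. Neurofilament and axonal cytoskeleton genes had a mean log2 difference of 0.04 over 24 members (camera adjusted p = 0.699), and axonal transport motors -0.03 over 27 (adjusted p = 0.722). Unfolded protein response genes were at -0.05 over 21 members (adjusted p = 0.699), heat shock chaperones at 0.13 over 21 (adjusted p = 0.688) and splicing factors at -0.01 over 59 (adjusted p = 0.84). Nuclear-encoded oxidative phosphorylation genes were at -0.03 over 78 members (adjusted p = 0.568). Without wild type replicate 1 they passed, at -0.09 with 11 of 78 higher (adjusted p = 0.00369). Neuronal injury and regeneration genes had a mean of -0.07 but a median of 0.14 over 23 members, with the test leaning upward (adjusted p = 0.401), and passed without wild type replicate 1 at 0.26 (adjusted p = 0.00489).

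The differences of both mutants from wild type were compared across 16338 genes, which are not independent replicates. Pearson's r was 0.58 with a covariance of 0.272, and 72.8% of genes had the same sign. Both differences use the same wild type libraries. Simulated counts without any change were drawn for all 12 libraries, wild type included, with 1 mean per gene. They gave an r of 0.48 to 0.53, a covariance of 0.206 to 0.241 and the same sign in 65.9% to 67.4% of genes. Each gene was drawn on its own, so the simulation lacked any likeness between libraries, such as that of heterozygote replicate 1 and homozygote replicate 1. Values above its range therefore do not show a shared effect of the mutation. With a separate pair of wild type libraries for each mutant, r averaged 0.11 over 6 splits, from 0.09 to 0.14, and the same sign was found in an average of 56% of genes. Without heterozygote replicate 1 and homozygote replicate 1, r was 0.418 and the average over the splits was -0.013.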

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

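The tests of interneuron content, of an effect in every mutant library, of the Spop explanations, and of genotype and total mitochondrial RNA in the mitochondrial pattern were chosen after the results were seen. In groups of 4 libraries, a library was singled out where its gap to the nearest other, divided by the range, was above 0.829. Chance alone singles out about 1 in 20 groups, or 7.2 of the 144 screened, and 16 were found.

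Heterozygote replicate 1 and homozygote replicate 1 were singled out by marker scores and genes detected. In homozygote replicate 1 the inhibitory interneuron score was -2.18 against 3.60 to 4.27 in the other homozygotes (gap ratio 0.896), and the Schwann cell and root score was 1.42 against 3.22 to 3.56 (0.843). That score has 3 tested members and dropped through 2310046A06Rik (0 CPM) and A330049M08Rik (0.798 CPM), while the most abundant, Pmp22, was higher there, at 823 CPM against 120 to 346 CPM in the 10 libraries other than this one and heterozygote replicate 1. In heterozygote replicate 1 the excitatory interneuron score was -1.72 against 1.40 to 2.03 (0.834), and genes detected were the fewest of the group, at 16312 (0.874).

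A general loss of transcripts of similar abundance is argued against, since 17 of 3922 genes at 50 to 500 CPM (0.43%) were over 8-fold lower in both of these libraries, while all 5 interneuron markers in that range were. A loss of this size in every mutant library is argued against too: the other 6 mutant libraries had inhibitory interneuron scores of 3.26 to 4.27. Of these 6, 0 lay below the lowest wild type library, but that bound was wild type replicate 1 alone, at 3.20. Heterozygote replicate 4 (3.26) and homozygote replicates 3 (3.60) and 4 (3.61) lay below the other wild type libraries (3.77 to 5.0). A smaller effect of the mutation therefore stays open. Fewer interneurons in the captured material is a candidate explanation: 12 of 17 interneuron markers lay below the range of the other 10 libraries in both, and 13 of 19 motor neuron markers lay above it, while Esrrg lay below it. Both libraries were singled out by such markers, so these counts describe the pattern and cannot test the explanation. Of the 10 inhibitory markers, 2 are also held by another list, and 12 of the 20 motor neuron markers written down are. A difference between the animals stays open, as does a difference in the capture: replicate 1 had the highest motor neuron score in every genotype (7.29, 7.84 and 7.73), but the labels give no capture date.

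Spop was lower with each mutant allele, and it lies on chromosome 11 while Tardbp lies on chromosome 4. A difference in interneuron content as the whole cause is argued against, since the homozygote difference was -0.61 (SE 0.07) with all libraries and -0.61 (SE 0.08) without both libraries poor in interneuron RNA, where the adjusted p was 0.0847 with fewer libraries, against 9.81e-12 to 0.263 over all settings. Reads moved to its paralog Spopl are argued against as well, since the gain of Spopl, 2.89 CPM, came to 5.1% of the loss of Spop, 56.5 CPM. Chance could not be excluded: 2 of the 35 splits of the 8 homozygote and wild type libraries gave at least 1 gene (real 1, highest other 1), and 9 of 100 splits did so for the allele slope (real 1, highest other 4). An effect of the mutation stays open as a hypothesis that was found and tested on the same libraries.

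The 6 mitochondrially encoded genes from mt-Co2 to mt-Nd4l varied over 100-fold between libraries. A difference between the genotypes is argued against, since mt-Co3 alone ranged 270-fold among the wild type libraries. A difference in all mitochondrial RNA is argued against, since the sum of the other 7 genes varied 1.31-fold. Reads shared with a nuclear copy are a candidate explanation: 5 of the 6 genes have an annotated copy on chromosome 1, between 24612407 and 24615565, that is 100% identical over at least 98.3% of the gene, while 0 of the other 7 has a copy of at least 99% identity over at least 95% of the gene, although a copy identical over 63.6% of mt-Nd4 lies beside them and mt-Nd4 varied 1.69-fold. Why the libraries would differ in this stays open, as does a change in the sequence of the mitochondrial chromosome between animals.

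The other libraries singled out are given as values. The share of mitochondrially encoded genes was 0.968% in homozygote replicate 3 against 0.735% to 0.765% (gap ratio 0.874). Tardbp was lowest in wild type replicate 1, at 5.96 log2 CPM against 6.25 to 6.30 (0.854). Aox1 was highest in wild type replicate 4 (0.966), Wwp2 lowest in heterozygote replicate 2 (0.841) and Cwc25 lowest in wild type replicate 2 (0.857). Cpne9 was lowest in wild type replicate 2 (0.832). Fasl was highest in wild type replicate 4 (0.844) and lowest in homozygote replicate 4 (0.959). Ratios of 1 came from genes with 0 counts in the other libraries of the group: Gfpt2 with 1 count in heterozygote replicate 1, Ggt1 with 13 counts in heterozygote replicate 3, and Ptpn6 with 15 counts in wild type replicate 1 and 1 count in heterozygote replicate 1.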

How the results depend on the processing

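Leaving out both libraries poor in interneuron RNA and the interneuron covariate were chosen after the data were seen. Of 112 summary values under other settings, 92 counted as unchanged. For counts of calls this meant within 1.5 times the count or staying at 0, and for r within the SD of its leave-one-out values. For Tardbp it meant the same sign and the same side of the threshold, whatever the size of the move. The cause of the moves was not tested except where fewer libraries entered. DESeq2 gave 13, 9, 3, 12 and 5 genes for homozygotes against wild type, heterozygotes against wild type, the mutants, the slope and any difference; of the first 13, 4 had at least 4 libraries at 0. The replicate number was not taken to pair libraries, since 4 of 12 resembled a library of their own number best. The replicate 1 library of every genotype was among these. With the genotype means removed, wild type replicate 1 correlated at 0.11 with either mutant replicate 1, and the mutants at 0.45. A batch shared by replicate 1 therefore stays open. A block for the replicate number gave 6 genes for homozygotes and 4 for the slope, and 8 lists for heterozygotes. Homozygotes had 0 calls with genes detected as a covariate, with only the 8 libraries compared and without both libraries poor in interneuron RNA. List calls were 0 in every comparison with an estimated correlation and with fry; they were 2 for homozygotes without both libraries and 3 for heterozygotes with the interneuron covariate. Splitting the wild type libraries gave an r of 0.11. On leaving out each library in turn, gene calls ran from 0 to 1 for homozygotes and 0 to 2 for the slope, and stayed at 0 elsewhere. List calls ran from 0 (without homozygote replicate 1) to 7 (without wild type replicate 1) for homozygotes (1 without wild type replicate 4), from 2 (without wild type replicate 4) to 8 (without wild type replicate 1) for heterozygotes (3 without wild type replicate 3) and from 3 to 6 (without heterozygote replicate 3 or homozygote replicate 1; 5 without heterozygote replicate 1 or 4) between the mutants. The r ran from 0.42 (without heterozygote replicate 1) to 0.65 (without wild type replicate 1). Tardbp ran from -0.03 to 0.07 for homozygotes, -0.08 to 0.04 for heterozygotes, 0.00 to 0.08 between the mutants and -0.01 to 0.04 for the slope, with a reversed sign without wild type replicate 1 in the first and last. The TDP-43-dependent list ran from -0.04 to 0.01 in heterozygotes (0.01 without heterozygote replicate 4), and the ALS and FTD list from -0.03 to 0.05 between the mutants (-0.01, -0.01 and -0.03 without heterozygote replicate 4 and homozygote replicates 2 and 3). Of 502 values under other settings for the single genes and lists followed, cholesterol synthesis genes not among them, 441 kept side and direction, 37 no longer passed, 24 newly passed and 0 reversed. On leaving out each library, of 816 such values 40 no longer passed and 4 reversed, and of 156 summary values 27 moved and 6 reversed, all 6 for Tardbp. Cholesterol synthesis genes in homozygotes, at 0.08 (adjusted p = 0.401), turned direction between settings: they passed as lower with the interneuron covariate (-0.13, adjusted p = 0.0427) and as higher without wild type replicate 1 (0.19, adjusted p = 0.0209). A covariate for Y-linked transcripts was not run, because all libraries had them. The effect of depth was not tested; the simulation recovered 9.68% of genes changed 1.5-fold and 19.4% of those at 32 CPM or more.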

Other observations

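The genes of the first paragraph were chosen after their values were seen, and the splits of the libraries were set before. Wild type replicate 1 and homozygote replicate 4 lay apart from the other libraries on the second principal component, with 10% of the variance. Ecel1, an endopeptidase that neurons make after nerve injury, was at 608 and 304 CPM in these libraries, against 64.7 to 220 CPM in the other 10. Lcn2, the iron-binding lipocalin, was at 129 and 118 CPM against 1.36 to 60.2 CPM, and Scn9a, a sodium channel of sensory neurons, at 116 and 82.9 CPM against 18.1 to 51.2 CPM. The tubulin gene Tubb6 was at 92.4 and 62.2 CPM against 12.9 to 32.7 CPM, and Clic1, a chloride channel gene, at 122 and 82.2 CPM against 0.352 to 49.8 CPM. Jun, Gal and Atf3 did not set both libraries apart. Jun was at 122 and 81.5 CPM against 36.7 to 89.9 CPM, Gal at 30.7 and 1.91 CPM against 0.166 to 8.84 CPM, and Atf3 at 1.08 and 0 CPM against 0 to 1.83 CPM.

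The number of calls was compared with that from other splits of the same libraries. For single genes the real number was 0 for heterozygotes against wild type, between the mutants and for any genotype difference. Every split reaches 0, so 35 of 35 (highest other 0), 35 of 35 (highest other 0) and 100 of 100 (highest other 11) decide nothing. For lists, 28 of 35 splits gave at least the 4 of homozygotes against wild type (highest other 13), 26 of 35 at least the 5 of heterozygotes (highest other 17) and 24 of 35 at least the 3 between the mutants (highest other 13). Chance could not be excluded for the lists. Splits that call several times the real number point to a structure of the samples. Those with 11 genes put wild type replicate 1, heterozygote replicate 1 and homozygote replicates 1 and 4 in a single group.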
